A study of Saccharomyces cerevisiae and Homo sapiens with 62 samples.

How the data were processed

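The series measured where sequence-specific DNA-binding proteins sit on the genome of budding yeast, Saccharomyces cerevisiae strain BY4741. ChIP-exo was run on cells and PB-exo, Native PB-seq and WhIP-exo were run in vitro. In an exo assay an exonuclease trims the immunoprecipitated DNA strand by strand up to the crosslinked protein, so that a bound site gives a pair of peaks, 1 per strand. Per the labels' protocols, cells for ChIP-exo were grown at 25 °C and crosslinked with 1% formaldehyde, PB-exo and WhIP-exo reactions with 0.05%, and Native PB-seq reactions were left uncrosslinked. Per the same protocols, the in vitro complexes were recovered by antibody from sonicated genomic DNA, and the ChIP-exo complexes by IgG from sonicated nuclei. The labels do not define WhIP-exo beyond its crosslinking and its in vitro source.

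Samples were grouped by factor and assay, as their titles give them, into 18 groups of 62 samples. The authors deposited 15 lists of peak pairs, 1 for each group with a factor, made over all replicates of the group together. For this reason no value here has a replicate error, and no replicate could be left out. The tests describe the listed peaks of pooled libraries, and their p-values say nothing of the spread between cultures or reactions. The 3 groups of controls, with 4 samples, had no list and were not analysed here, so the peaks could not be set against a background measured in the same way. The labels of the Reb1 PB-exo samples, on yeast and human DNA, and of the Reb1 Native PB-seq samples name a Rap1-TAP antibody, and the source of the Reb1 Native samples reads in vivo. These groups were kept under the factor in their titles, and a check of the yeast lists is given with the Reb1 results.

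Per the submitters' processing notes, base calls came from CASAVA 1.7 or bcl2fastq 2.16, reads were handled with BWA 0.7.9a, and the yeast build was sacCer3. The lists name cwpair as the program that paired the peaks. The filter behind the filtered lists, the peak caller and its settings, and the human build are not given in the sources used here. Each list gives a position per pair, a score deposited by the authors, and the distance in bp between the forward-strand and reverse-strand peaks of the pair. The authors' score is a whole number whose definition is not given. It was used only to rank or filter peaks within a list, because scores of different lists need not share a scale. Pair distances reached 80 bp in the exo lists and 400 bp in the Native lists. The lists give no read totals, so the depth behind each list is unknown. A list with more peaks may come from more reads, a higher protein concentration or another threshold, and list lengths were therefore not compared as amounts of binding. A pair that reaches no list may have been lost to the threshold, so a missing peak does not show that a site was unbound.

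Genes were taken from a table of assembly R64, the assembly behind sacCer3, with 6002 protein-coding genes on 16 nuclear chromosomes. The spans hold no UTRs, since 96.4% of the lengths were multiples of 3, and are called coding spans. Strand came from the W or C of the systematic name, and 19 coding genes without either letter were given no promoter. A promoter was the 500 bp upstream of the start of a coding span. A peak was classed as promoter when it lay in a promoter and in no coding span, as coding when it lay in a coding span, and as other otherwise. For genes and gene lists a gene counted as bound when its promoter held a peak, whether or not that position was also in the coding span of a neighbour. The same classes over 120700 positions spaced 100 bp apart gave the genome background.

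Peaks of different lists were called shared when their positions lay within 50 bp of each other. The share of peaks carries a 95% Wilson interval, which covers counting error only. Chance was taken from 1000 circular shifts of the other list along each chromosome, in a one-sided permutation test whose smallest p is 0.001. The shifts do not keep the concentration of peaks in promoters, at chromosome ends or at tRNA genes. The promoter share of PB-exo peaks with and without a ChIP-exo peak was compared by a two-sided Fisher's exact test. Scores were compared by the probability that a shared peak outranks an unshared peak of the same list, with 100000 permutations and a smallest p of 1e-05. Tests on promoter shares and on scores counted listed pairs of the same site as separate peaks. Their p-values are too small where a site has several pairs, and these tests were not repeated on merged positions. For 11 gene lists, fixed before the data were examined, promoters with a peak were counted against those of all other coding genes by a two-sided Fisher's exact test over 154 pairs of gene list and peak list. The gene lists were ribosomal proteins, glycolysis and fermentation, sulfur amino acid synthesis, the phosphate regulon, a- and alpha-specific genes, G2/M and M/G1 cell cycle genes, ribosome biogenesis, RNA polymerase subunits, the proteasome, histones and galactose genes. All list members were found in the gene table. tRNA genes with a peak within 100 bp and chromosome ends with a peak within 1 kb were counted against the same shifts. A chromosome was taken to end at its last annotated gene or last listed yeast peak, whichever lay further. Distances to that end can therefore fall short of the true ones. The other end was the start of the coordinates. Adjusted p-values are Benjamini-Hochberg values within each family of tests, with 0.05 as the threshold.

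Genes named in the text follow a rule fixed before the data were examined. For each factor with both assays they are the 8 genes whose promoters hold the highest-scoring ChIP-exo peaks with a PB-exo peak, the 4 with the highest-scoring ChIP-exo peaks that lack a PB-exo peak, and the 4 highest-scoring PB-exo peaks without a ChIP-exo peak. For each Native and WhIP list and for Pho4 they are the 4 highest-scoring peaks, and for each gene list past its test up to 4 members in order of score. A peak between divergent genes counts for both genes.

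The alternatives were a shared distance of 20 or 100 bp, peaks at or above the median score of their list (of the PB-exo list alone for the promoter odds ratios), peaks of a list merged within 50 bp, promoters of 300 or 1000 bp, and removal of peaks within 20 kb of a chromosome end or in the rDNA array of chromosome XII (450 to 490 kb). After the data were seen, removal of pairs exactly 3 bp apart and of peaks within 100 bp of a tRNA gene were added, and for the promoter odds ratios also removal of chromosome ends and rDNA and the median score in both lists. No genome sequence and no centromere positions were used here, so the planned counts of motifs, flanking bases, E-boxes and centromeres were not run. For the human DNA only counts and shares on the 22 autosomes were made, and the sex chromosomes were left out.

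The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The code was tested on simulated data. For simulated lists set against the Reb1 PB-exo list with 20% or 50% of 1000 peaks copied, the recovered shares were 24.2% and 52.5%, against 24.2% and 52.6% expected with chance hits added, and 20 of 20 runs passed at each size. With nothing copied 2 of 20 runs passed. The peaks not copied were placed evenly at random along the chromosomes, and fewer shifts were made than for the real lists. Clustered pairs and a concentration in promoters, as in the real lists, were therefore not part of this check. An odds ratio of 5 over 2000 simulated PB-exo peaks came back as 5.01, and 6 of 100 runs with an odds ratio of 1 passed. In simulated gene lists over 6002 genes, 215 of 220 tests were called when 60% of members against 10% of other genes were bound, and 8 of 220 when no difference was made.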

Results

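The lists covered 5 yeast general regulatory factors, Abf1, Cbf1, Mcm1, Rap1 and Reb1, each in cells by ChIP-exo and on purified genomic DNA by PB-exo, and the phosphate regulator Pho4 by PB-exo. The comparison of both assays asks how much of the binding seen in cells occurs where the protein meets bare genomic DNA. ChIP-exo was made from 5 samples for Abf1, 5 for Cbf1, 3 for Mcm1, 4 for Rap1 and 5 for Reb1. PB-exo was made from 3 samples for Abf1, 2 for Cbf1, 2 for Mcm1, 4 for Rap1, 12 for Reb1 and 2 for Pho4. Abf1, Rap1 and Reb1 were used at 100 nM, Cbf1 and Mcm1 at 1 uM and Pho4 at 50 nM. Abf1 and Reb1 were also tested by Native PB-seq, without crosslinking and without exonuclease (3 samples each). Reb1 was further tested by WhIP-exo (3 samples) and on DNA of MCF-7, an established human breast cancer cell line (2 samples, 1 uM). Each group had a single list over its pooled samples, so no value has a replicate error, and read depth is unknown.

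The ChIP-exo lists held 3214 peaks for Abf1, 934 for Cbf1, 630 for Mcm1, 387 for Rap1 and 3180 for Reb1. The PB-exo lists held 1958, 1061, 903, 17272 and 7018 in the same order, and 5693 for Pho4. Several listed pairs can mark a single site. Merging those within 50 bp left 1574, 540, 389, 264 and 1712 positions in the ChIP-exo lists. Promoters, the 500 bp upstream of start codons, made up 16.03% of the genome and coding spans 72.8%. In ChIP-exo the promoter share of peaks was 38.9% for Abf1, 46.5% for Cbf1, 47.5% for Mcm1, 46.0% for Rap1 and 58.6% for Reb1. In PB-exo it was 21.8%, 43.0%, 30.8%, 22.2% and 31.8% in the same order. The median distance between the paired strands in ChIP-exo was 21 bp for Abf1, 26 bp for Cbf1, 25 bp for Mcm1, 22 bp for Rap1 and 26 bp for Reb1.

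For every factor, more ChIP-exo peaks had a PB-exo peak within 50 bp than under shifted positions, and the share ran from 16.3% for Abf1 to 97.9% for Rap1. A longer PB-exo list also meets more peaks by chance, and relative to the shifts Rap1, with the longest list, had the lowest excess (8.30 times) and Cbf1 the highest (72.2 times). The Rap1 excess was near the most it could be, with 11.8% shared under shifts and nearly all peaks shared. Without pairs 3 bp apart it was 12.4 times, and Reb1 was lower at 12.2 times. Permutation p was 0.001 for each of the 5 factors, the smallest that 1000 shifts can give. The shifts do not keep the concentration of peaks in promoters, so an excess over them need not be particular to a factor. ChIP-exo lists of different factors also coincided above shifts, as given below. Outside chromosome ends, rDNA and tRNA genes, Reb1 PB-exo peaks stood at Rap1 ChIP-exo peaks 2.84 times as often as under shifts, and at Reb1 ChIP-exo peaks 13.5 times. Scores separated the shared peaks from the others in each PB-exo list. In the 10% of each list with the highest scores, 65.8% of Abf1, 88.8% of Cbf1, 51.6% of Mcm1, 28.8% of Rap1 and 67.5% of Reb1 PB-exo peaks had a ChIP-exo peak. In the 10% with the lowest scores these shares were 3.08%, 25.5%, 16.7%, 0.0579% and 6.56%.

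**Figure D1:**
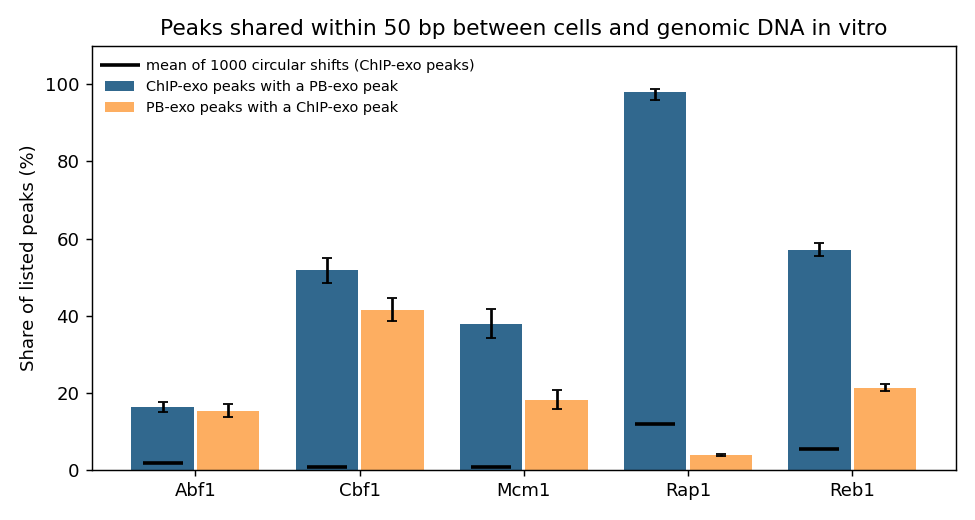
Share of listed peaks, in percent, with a peak of the other assay within 50 bp, for the 5 factors. Bars give ChIP-exo peaks with a PB-exo peak and PB-exo peaks with a ChIP-exo peak, error bars are 95% Wilson intervals, and black lines are the mean of 1000 shifts for the ChIP-exo bars; Rap1 reached 97.9% in 1 direction and 3.82% in the other.

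**Figure D2:**
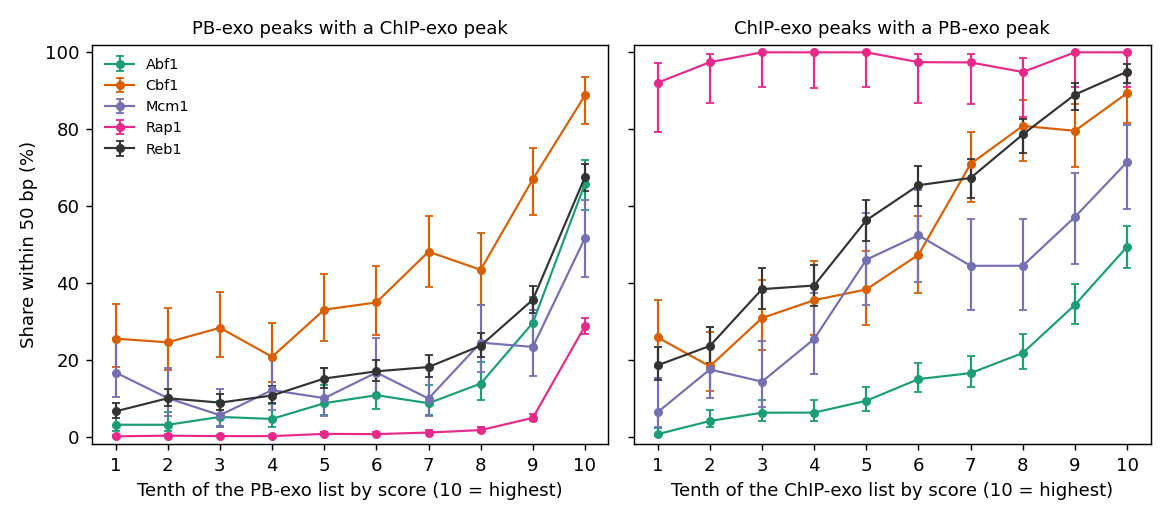
Share of peaks shared within 50 bp, in percent, in 10 equal parts of a list ranked by the authors' score, from 1 (lowest) to 10 (highest), with 95% Wilson intervals. The left panel shows PB-exo peaks with a ChIP-exo peak, where the highest part ran from 28.8% (Rap1) to 88.8% (Cbf1), and the right panel ChIP-exo peaks with a PB-exo peak, where it ran from 49.4% (Abf1) to 100% (Rap1).

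Rap1, a regulator of ribosomal protein genes and a telomere-binding protein, had a ChIP-exo peak in the promoters of 69 of 137 ribosomal protein genes (50.4%), against 1.84% of other genes (odds ratio 54.1, adjusted p = 4.10e-71, Fisher's exact test). Its PB-exo peaks reached 115 of the 137 (83.9%, against 42.1%; odds ratio 7.17, adjusted p = 1.96e-21), and all 69 promoters bound in cells were among them. In ChIP-exo 29 of the 137 had a peak with 300 bp promoters (odds ratio 24.7), and 8 among peaks at or above the median score (odds ratio 16.5), and both passed. RPS24A, with its coding span at 306323 to 307196 of chromosome V, carried its ChIP-exo peak at V 305995, which is 328 bp upstream (score 710), and a PB-exo peak 5 bp away. RPL1B (VII 254353, score 280), RPL2B (IX 316370, score 279) and RPS1B (XIII 146113, score 275) followed. In PB-exo the highest ribosomal protein promoters were RPS9A (XVI 404712, score 54324), RPS18A (IV 1359616, score 52455) and the divergent pair RPL13B and RPS16A (XIII 551616, score 39420). Glycolytic and fermentation genes were bound more often than other genes in PB-exo, at 15 of 19 promoters (78.9% against 43.0%, odds ratio 4.97, adjusted p = 0.0149), led by ENO1, GPM1, PGI1 and FBA1. In ChIP-exo 3 of 19 had a peak, which did not pass (adjusted p = 0.0984), while 5 of 19 did with 1000 bp promoters, which passed (odds ratio 7.89, adjusted p = 0.0114). The PB-exo call was lost with 300 bp promoters (8 of 19, odds ratio 1.79, adjusted p = 0.812) and with 1000 bp promoters (18 of 19, odds ratio 8.57, adjusted p = 0.0807).

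Of the 387 Rap1 ChIP-exo peaks, 379 had a PB-exo peak (97.9%, interval 96.0 to 98.9), 8.30 times the 11.8% under shifts, at a median distance of 4 bp. With pairs within 50 bp merged in both lists and placed at their mean, the share was 66.3% (175 of 264 positions, interval 60.4 to 71.7). Before merging only 8 of the 387 peaks lacked a PB-exo peak. The fall therefore comes mainly from mean positions that moved apart, and is not a share of sites without a PB-exo peak. In the other direction 660 of 17272 PB-exo peaks (3.82%) had a ChIP-exo peak. Among genes away from chromosome ends, the highest shared ChIP-exo peaks were at GPD1, a glycerol 3-phosphate dehydrogenase gene (IV 411457, score 1636), SNF4, which encodes a subunit of the Snf1 kinase complex (VII 291803, 1019), TEF1, which encodes translation elongation factor 1 alpha (XVI 700165, 781), RPS24A and HOM6, a homoserine dehydrogenase gene (X 690721, 369). YCR108C, YNR077C and YOL166W-A also stood among the 8 genes, with scores of 9270, 2368 and 821. Their peaks lay at 46, 382 and 155 bp from the end of their chromosome, as that end was taken here. Of the 8 ChIP-exo peaks without a PB-exo peak, those of highest score in a promoter lay upstream of 4 genes. These were YNR077C and YCR108C again, at 335 and 117 bp from the end, GPR1, a glucose receptor gene (IV 392162, 194), and VHR2 (V 284440, 30). The PB-exo peaks of highest score without a ChIP-exo peak were in the coding span of RPC37, a subunit of RNA polymerase III (XI 488221, 48062), between CCA1 and RPH1 (V 522908, 43309), and at XIV 349342 and XI 642861, outside promoters and coding spans.

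Rap1 PB-exo peaks with a ChIP-exo peak lay in promoters in 345 of 660 cases (52.3%), against 3492 of the 16612 others (21.02%; odds ratio 4.11, adjusted p = 2.84e-66, Fisher's exact test). Several of the 660 peaks can mark a single site. Merging pairs within 50 bp left 181 PB-exo positions with a ChIP-exo position. That number can undercount the separate sites, because merged positions are means and can move apart. Coding spans held 9.55% of the shared and 67.8% of the other PB-exo peaks. A shared peak outranked an unshared peak with probability 0.928 (medians 2240 and 215, permutation p = 1e-05, the smallest possible). The odds ratio was 2.47 with 300 bp promoters and 9.24 without the chromosome ends and rDNA. The excess was lost among peaks at or above the median score of both lists, an alternative added after the data were seen (68 of 264 shared and 2187 of 8398 other PB-exo peaks in promoters, odds ratio 0.985, adjusted p = 0.943). Of the 194 ChIP-exo peaks in that part, 111 (57.2%) lay within 1 kb of a chromosome end.

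Reb1, which terminates transcription at the rDNA and binds many RNA polymerase II promoters, had a ChIP-exo peak in the promoters of 1016 of 6002 coding genes. Its highest ChIP-exo peak stood at XII 371292, 328 bp upstream of HOG1, the osmotic stress MAP kinase gene (coding span XII 371620 to 372927), with a score of 4547 and a PB-exo peak at the same position. YTM1, a ribosome biogenesis gene (XV 832619, score 2920), NAT2 (VII 787127, 2777), YLR162W, whose peak lay in the span of chromosome XII taken as rDNA (XII 489472, 2291), BPH1 (III 179308, 2190), HSH49, a splicing factor gene (XV 912641, 2005), IGO1 (XIV 340146, 1913) and SEC61, which encodes the pore of the endoplasmic reticulum translocon (XII 877550, 1796), made up the rest of the 8 genes. The IGO1 and SEC61 peaks also lay in the coding spans of the neighbours PGA1 and YLR379W-A. Peaks without a PB-exo peak lay between MRPS17 and GCV2 (XIII 637183, 1413), 349 bp from the end of chromosome XIV upstream of YNR077C (1133), and upstream of RPT2 (IV 437851, 1048), where the peak was within 100 bp of a tRNA gene. PB-exo peaks without a ChIP-exo peak were highest in the coding spans of CDC19, the pyruvate kinase gene (I 72811, 9971), and ECM32 (V 542770, 9076), and upstream of RCF1 (XIII 216314, 9580) and UTP20 (II 227391, 8185).

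A Reb1 PB-exo peak stood within 50 bp of 1817 of 3180 ChIP-exo peaks (57.1%, interval 55.4 to 58.8), 10.9 times the 5.24% under shifts, at a median distance of 14 bp. In the other direction 1495 of 7018 PB-exo peaks (21.3%) had a ChIP-exo peak. Peaks at tRNA genes made up 17.5% of the ChIP-exo list, and without them the share was 67.4% (1768 of 2622). Shared PB-exo peaks were in promoters in 1031 of 1495 cases (69.0%), against 1202 of 5523 (21.8%; odds ratio 7.99, adjusted p = 4.54e-249, Fisher's exact test). Coding spans held 10.9% of shared and 67.9% of other PB-exo peaks, and a shared peak had the higher score with probability 0.752 (medians 1860 and 1048, permutation p = 1e-05). Without chromosome ends and rDNA the odds ratio was 12.6.

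Proteasome genes were the gene list that Reb1 bound more often than other genes in every assay, with promoters of 500 bp. ChIP-exo peaks stood in 15 of 33 promoters (45.5% against 16.8%, odds ratio 4.14, adjusted p = 0.00133), and PB-exo peaks in 21 (63.6% against 31.5%, odds ratio 3.803, adjusted p = 0.00214), with all 15 among the 21. WhIP-exo reached 14 (42.4%, odds ratio 3.43, adjusted p = 0.00787) and Native PB-seq 11 (33.3%, odds ratio 6.69, adjusted p = 0.000131). With 1000 bp promoters PB-exo (23 of 33, odds ratio 2.62, adjusted p = 0.0840) and WhIP-exo (14 of 33, odds ratio 2.35, adjusted p = 0.126) did not pass, and at or above the median score Native PB-seq had 7 (odds ratio 6.06, adjusted p = 0.00450). In ChIP-exo the highest were PRE3 (X 434812, score 1119), RPT2, RPT5 (XV 544852, 918) and RPT1 (XI 174016, 833), genes of the catalytic core and of the ATPase ring. PRE4 had the highest-scoring proteasome promoter in PB-exo (VI 250019, 12194) and WhIP-exo (VI 250020, 15099), and the peak at RPT1 was among the first 4 members in all 4 lists. In WhIP-exo, 11 of 137 ribosomal protein promoters had a peak, fewer than among other genes (8.03% against 18.04%, odds ratio 0.397, adjusted p = 0.0117). This was the only depletion that passed over the 154 pairs, and it did not pass with 1000 bp promoters (21 of 137, adjusted p = 0.0925) or at or above the median score (8 of 137, adjusted p = 0.0826). Adjusted over the list alone 2 passed, the other being Abf1 Native PB-seq at 13 ribosomal protein promoters (odds ratio 0.475, adjusted p = 0.0315, and 0.0630 over all pairs).

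The uncrosslinked Reb1 list held 586 peaks, with a promoter share of 62.8%. Of these, 402 had a PB-exo peak (68.6%, interval 64.7 to 72.2; 13.1 times chance) and 456 a ChIP-exo peak (77.8%, interval 74.3 to 81.0; 46.1 times chance). Permutation p was 0.001 for both. The highest scores stood at XII 1071594, 6304 bp from a chromosome end, and upstream of YGR054W (VII 596420, score 4101), MRPS17 and GCV2 (XIII 637198, 3328) and AFG3 (V 192211, 2614, inside the coding span of SPC25). At MRPS17 and GCV2 the ChIP-exo peak had no PB-exo peak within 50 bp, and the highest PB-exo peak elsewhere in the promoter scored 1723. With a distance of 20 bp, 41.3% of Native peaks had a PB-exo peak. Native pairs were 142 bp apart in the median, against 20 bp in PB-exo. Native PB-seq lacks both crosslinking and exonuclease, so effects of crosslinking and of resolution on these shares cannot be told apart. The comparison with ChIP-exo was added after the data were seen.

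WhIP-exo gave 3489 Reb1 peaks, of which 55.2% were in promoters. PB-exo peaks stood at 1968 of them (56.4%, interval 54.8 to 58.0; 10.7 times chance) and ChIP-exo peaks at 1860 (53.3%, interval 51.7 to 55.0; 31.7 times chance), with permutation p = 0.001 for both. In the other direction 1962 of 3180 ChIP-exo peaks (61.7%) had a WhIP-exo peak. The leading promoters were NMD3, a nuclear export factor gene of the large ribosomal subunit (VIII 443629, score 20514), PSD1, a phosphatidylserine decarboxylase gene (XIV 317904, 18290), NOP16 (V 156626, 17146), and CMR2 and ARF3 (XV 502616, 16665). After merging pairs within 50 bp, the share of WhIP-exo positions with a ChIP-exo position was 35.3%. Merged positions are means and can move apart, so this share can fall without any loss of shared sites.

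The Reb1 PB-exo and Native samples carry a label naming a Rap1-TAP antibody, so their lists were set against the ChIP-exo peaks of both factors, without chromosome ends, rDNA and tRNA genes. PB-exo peaks stood at 1487 of 2234 Reb1 ChIP-exo peaks (66.6%) and at 30 of 218 Rap1 ChIP-exo peaks (13.8%), both above the 4.94% and 4.85% under shifts (permutation p = 0.001 for each). These were 13.5 and 2.84 times the shifts. Of the same 218 Rap1 peaks, 26 (11.9%) had a Reb1 ChIP-exo peak, so a share of this size at Rap1 peaks was also found for Reb1 in cells. Native peaks stood at 724 of the 2234 (32.4%) and at 3 of the 218 (1.38%, permutation p = 0.076).

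Cbf1, a basic helix-loop-helix protein of centromeres and of methionine synthesis genes, had ChIP-exo peaks in 14 of 27 promoters of sulfur amino acid genes (51.9% against 4.95%, odds ratio 20.7, adjusted p = 1.73e-10, Fisher's exact test). PB-exo peaks stood in 15 (55.6% against 4.82%, odds ratio 24.7, adjusted p = 7.27e-12), and 13 promoters had both. With 300 bp promoters the counts were 6 (odds ratio 10.8) and 9 (odds ratio 16.1), and with 1000 bp 14 (odds ratio 13.1) and 15 (odds ratio 15.8), all of which passed. In cells the leading members were CYS3, the cystathionine gamma-lyase gene (coding span I 130799 to 131983, peak at I 130587, score 141), MET6, the methionine synthase gene (V 342640, 140), MET2 (XIV 116998, 133) and SUL2, a sulfate permease gene (XII 323231, 117). In vitro they were MET13 (VII 272020, 1904, inside the coding span of SCS3), MET10 (VI 213081, 1375), MET28 (IX 384343, 1069) and MET3 (X 455860, 1053).

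Among all genes the highest Cbf1 ChIP-exo peaks with a PB-exo peak were at YNG1, a subunit of a histone acetyltransferase complex (XV 446886, score 685), between IDH1 and NCE103, encoding an isocitrate dehydrogenase subunit and carbonic anhydrase (XIV 559399, 463), and at SPO23 (II 718541, 399), CKB2 (XV 405290, 384, inside the coding span of HIR2), DSE1 (V 409518, 370) and DPI8 with MRS3 (X 160181, 365). Those without a PB-exo peak were at TRA1 (VIII 302545, 257), SET2 with ERG20 (X 104743, 206) and the kinase gene SWE1 (X 79693, 200). PB-exo peaks without a ChIP-exo peak were highest in the coding spans of LUG1 (XII 832969, 2566), SBE22 (VIII 321127, 2228) and ECM14 (VIII 369481, 1829), and upstream of YIR042C (IX 436176, 2198). PB-exo peaks stood at 483 of 934 ChIP-exo peaks (51.7%, interval 48.5 to 54.9; 72.2 times the 0.717% under shifts), and 440 of 1061 PB-exo peaks (41.5%) had a ChIP-exo peak. Peaks at tRNA genes made up 24.6% of the ChIP-exo list, and without them the share was 68.5% (482 of 704). Shared PB-exo peaks were in promoters in 56.1% (247 of 440), the others in 33.7% (209 of 621; odds ratio 2.52, adjusted p = 3.64e-13, Fisher's exact test), and coding spans held 30.5% and 57.3%. A shared peak had the higher score with probability 0.715 (medians 802.5 and 458, permutation p = 1e-05). With 300 bp promoters the odds ratio was 1.61.

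Pho4, the activator of phosphate genes, binds the same E-box core as Cbf1. It had PB-exo peaks in 14 of 18 promoters of the phosphate regulon (77.8% against 17.6%, odds ratio 16.4, adjusted p = 8.24e-07, Fisher's exact test). These were led by PHO86 (X 192334, score 147), PHM6 (IV 1022588, 136), the acid phosphatase gene PHO5 (coding span II 429548 to 430951, peak at II 431210, 118) and VTC2, which encodes a subunit of the polyphosphate synthase complex (VI 131510, 95). Sulfur amino acid promoters were bound as well, 17 of 27 (63.0%, odds ratio 7.99, adjusted p = 3.67e-06), with SUL2, MET1, MET28 and MET22 first. Among peaks at or above the median score the odds ratio of the phosphate regulon was 29.9. Cbf1 PB-exo reached 4 of the 18 phosphate promoters, which did not pass (adjusted p = 0.0676). Of the Cbf1 PB-exo peaks, 598 of 1061 (56.4%, interval 53.4 to 59.3; 16 times chance, permutation p = 0.001) had a Pho4 peak, and 711 of 5693 Pho4 peaks (12.5%) had a Cbf1 peak. The concentrations differed, 1 uM for Cbf1 and 50 nM for Pho4. The highest Pho4 peaks were in the coding spans of SCH9 (VIII 509916, 396), RSC2 (XII 842573, 393) and SPO14 (XI 505779, 359) and upstream of SDD4 (XVI 607571, 310).

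Mcm1, a MADS-box protein of mating type and cell cycle control, had ChIP-exo peaks in 16 of 24 promoters of G2/M and M/G1 genes (66.7% against 3.03%, odds ratio 64.1, adjusted p = 2.97e-17, Fisher's exact test) and PB-exo peaks in 17 (70.8% against 4.20%, odds ratio 55.4, adjusted p = 6.82e-17), with 13 in both. BUD4 (X 598553, score 220), the replicative helicase gene MCM7 (II 625558, 146), CDC6 (X 69153, 141) and ACE2 (XII 407164, 94) led in cells, and SWI4 (V 386321, 3940), MCM7 (3633), MCM6 (2694) and CDC6 (1188) in vitro. Of 11 a- and alpha-specific genes, 6 had a ChIP-exo peak (54.5% against 3.19%, odds ratio 36.4, adjusted p = 7.19e-06), and these 6 and 4 more had a PB-exo peak (90.9% against 4.31%, odds ratio 222, adjusted p = 7.27e-12). The peak of highest score in the whole PB-exo list (XI 46498, 5268) stood 203 bp upstream of STE6, the a-factor exporter gene (coding span XI 42423 to 46295). MFA1, an a-factor gene (IV 1384956, 3246), STE2, the alpha-factor receptor gene (VI 82364, 3021), and AGA2, an agglutinin gene (VII 437120, 2537), followed. With 300 bp promoters the a- and alpha-specific odds ratio in ChIP-exo was 66.0, and with 1000 bp it was 21.3 in ChIP-exo and 119.7 in PB-exo. For the cell cycle genes it was 107.8 in ChIP-exo at or above the median score and 85.8 in PB-exo with 1000 bp promoters. The ChIP-exo scores were 85 for MFA2, 56 for STE2, 50 for STE6 and 36 for MFA1.

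The highest Mcm1 ChIP-exo peak stood between MTC6 and SPO12, a gene of mitotic exit (VIII 401196, score 307). It was followed, among peaks with a PB-exo peak, by JSN1 with BUD4, UTH1 (XI 519077, 179), YLR112W (XII 370611, 166, inside the coding span of YLR111W), ASE1, a spindle midzone gene (XV 436570, 156), and MCM7. Peaks without a PB-exo peak were at GLY1 (V 69204, 162), AIM20 (IX 46057, 85), CDC20 (VII 289503, 85) and YLR112W (XII 370659, 77). PB-exo peaks without a ChIP-exo peak were highest upstream of SFI1, inside the coding span of ORC3 (XII 142716, 4523), and in the coding spans of NDE1 (XIII 554899, 3123), FLC1 (XVI 134125, 2998) and ARR3 (XVI 941013, 2936). PB-exo peaks stood at 239 of 630 ChIP-exo peaks (37.9%, interval 34.2 to 41.8; 53.7 times the 0.706% under shifts), and 163 of 903 PB-exo peaks (18.1%) had a ChIP-exo peak. Peaks at tRNA genes made up 20.5% of the ChIP-exo list, and without them the share was 47.1% (236 of 501). Shared PB-exo peaks were in promoters in 64.4% (105 of 163), the others in 23.4% (173 of 740; odds ratio 5.93, adjusted p = 8.35e-23, Fisher's exact test), and coding spans held 4.91% and 64.1%. A shared peak had the higher score with probability 0.676 (medians 716 and 377.5, permutation p = 1e-05). The odds ratio was 3.95 with 300 bp and 15.8 with 1000 bp promoters, and 9.33 among peaks at or above the median score.

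Abf1 had ChIP-exo peaks in promoters of 10 of 30 RNA polymerase subunit genes (33.3% against 10.9%, odds ratio 4.07, adjusted p = 0.00827, Fisher's exact test) and of 10 of 33 proteasome genes (30.3%, odds ratio 3.54, adjusted p = 0.0161). The polymerase genes were led by RPC19 (XIV 412624, score 271), RPB8 (XV 761420, 145), RPC17 (X 414952, 87) and RPC25 (XI 176641, 77). The proteasome genes were led by RPN4 (IV 417061, 199), which encodes the transcription factor of proteasome genes and no subunit, RPN5 (IV 190720, 115), RPN8 (XV 817152, 86) and RPT2 (IV 437755, 73). The peaks at RPC17 and RPT2 were within 100 bp of a tRNA gene. At or above the median score 5 of the 30 polymerase genes had a ChIP-exo peak, which did not pass (odds ratio 2.37, adjusted p = 0.366). In PB-exo no gene list passed over all pairs with 500 bp promoters. RNA polymerase genes had 7 of 30 (odds ratio 3.42, adjusted p = 0.0636, and 0.0444 adjusted over the list alone) and ribosome biogenesis genes 10 of 53 (adjusted p = 0.0655). The polymerase genes passed with 1000 bp promoters (11 of 30, odds ratio 3.28, adjusted p = 0.0261) and the ribosome biogenesis genes with 300 bp promoters (8 of 53, odds ratio 3.43, adjusted p = 0.0314). In Native PB-seq, Abf1 was found at 23 of 53 ribosome biogenesis promoters (43.4% against 17.7%, odds ratio 3.58, adjusted p = 0.000170), with RRP7, UTP8, NOP58 and NOP14 first. It was also found at 15 of 30 polymerase promoters (50.0%, odds ratio 4.64, adjusted p = 0.000692), with RPO31, RPC82, RPB10 and RPO26 first, and at 14 of 33 proteasome promoters (42.4%, odds ratio 3.42, adjusted p = 0.00787), with PRE7, RPN1, RPN5 and PUP2 first.

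The highest Abf1 ChIP-exo peak in a promoter with a PB-exo peak stood at XIV 57825 between MCK1, a protein kinase gene (coding span XIV 56446 to 57573), and MRPS18, a mitochondrial ribosomal protein gene. It scored 422, and the PB-exo peak 7 bp away scored 7192. YET3 with BDF2 (IV 330859, 346), ECM25 (X 54249, 322), MRPL8 with COA3, which serve mitochondrial translation and cytochrome oxidase assembly (X 316605, 288), and OCA5 (VIII 48124, 274) followed. Peaks without a PB-exo peak stood between ARB1 and PHM8 (V 225583, 581), upstream of YOL166W-A at 575 bp from the end of chromosome XV (290), and upstream of KAE1 (XI 513337, 277), where the peak was within 100 bp of a tRNA gene. PB-exo peaks without a ChIP-exo peak were highest in the coding spans of ELO2, a fatty acid elongase gene (III 190596, 1795), LHS1 (XI 298817, 1777), MET10 (VI 213668, 1750) and TUB3, an alpha-tubulin gene (XIII 22589, 1750), of which the ELO2 and TUB3 pairs were 3 bp apart.

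PB-exo peaks stood at 525 of 3214 Abf1 ChIP-exo peaks (16.3%, interval 15.1 to 17.7; 10.2 times the 1.60% under shifts), and 300 of 1958 PB-exo peaks (15.3%) had a ChIP-exo peak. Peaks at tRNA genes made up 29.8% of the ChIP-exo list, and without them the share was 22.2% (502 of 2257). Of the PB-exo pairs, 1361 (69.5%) were exactly 3 bp apart, and among the other 597 the share with a ChIP-exo peak, in lists without such pairs, was 46.4%. Shared PB-exo peaks were in promoters in 69.3% (208 of 300), the others in 13.1% (218 of 1658; odds ratio 14.9, adjusted p = 2.40e-86, Fisher's exact test), and coding spans held 20% and 78.5%. A shared peak had the higher score with probability 0.819 (medians 808 and 262, permutation p = 1e-05). With a distance of 20 bp the ChIP-exo share was 10.6%, and without the 3 bp pairs the odds ratio was 8.07.

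The uncrosslinked Abf1 list held 1826 peaks, 59.9% of them in promoters. PB-exo peaks stood at 241 (13.2%, interval 11.7 to 14.8; 8.20 times chance) and ChIP-exo peaks at 480 (26.3%, interval 24.3 to 28.4; 16.7 times chance), with permutation p = 0.001 for both. Without pairs 3 bp apart, PB-exo peaks stood at 227 (12.4%, 26.2 times chance), and 222 of the 597 remaining PB-exo peaks (37.2%) had a Native peak. The highest peaks were between RIX7 and IRC19 (XII 73285, score 889) and upstream of GBP2 (III 103493, 830), HUA1 (VII 1026765, 815) and DSE1 (V 409507, 787). With a distance of 20 bp the share with a PB-exo peak was 6.30%. Native pairs were 169 bp apart in the median, so overlaps at short distances depend on resolution as well as on crosslinking.

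Over the 154 pairs of gene list and peak list, 20 were enriched and 1 depleted, and 21 and 2 when adjusted over the list alone. Histone genes had at most 3 of 10 and galactose genes at most 2 of 6 promoters with a peak in any list, and none of these passed. Whether a gene list was bound differently in cells and in PB-exo was tested by Fisher's exact test on the genes bound in a single assay. None of 55 pairs of factor and gene list passed after adjustment, and 1 had an unadjusted p under 0.05, ribosomal proteins for Mcm1 (0 in ChIP-exo alone and 9 in PB-exo alone, unadjusted p = 0.0151, adjusted p = 0.829). For Rap1 this test had little to work on, because 1 gene outside the ribosomal protein list, and none in it, was bound in ChIP-exo alone. Many pairs of the other factors also held few or no genes bound in a single assay. For Mcm1 at a- and alpha-specific genes, 0 in ChIP-exo alone and 4 in PB-exo alone gave an unadjusted p of 0.301. The lack of passing pairs therefore does not show that the gene lists were bound alike in both assays.

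**Figure D3:**
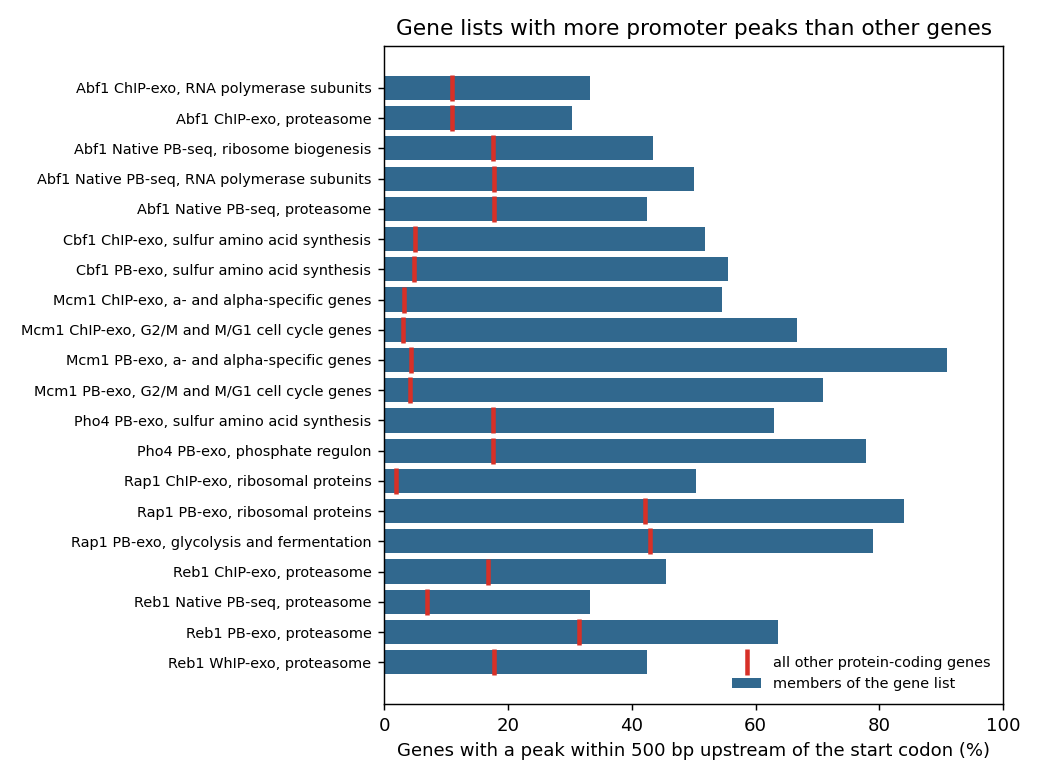
Share of genes, in percent, with a peak within 500 bp upstream of the start codon, for the 20 pairs of peak list and gene list that passed the enrichment test. Bars give the members of the gene list and red lines all other protein-coding genes; the highest bar is 90.9%, for Mcm1 PB-exo at a- and alpha-specific genes.

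tRNA genes carried ChIP-exo peaks of every factor tested in cells except Rap1. A peak stood within 100 bp of 271 of 275 tRNA genes for Abf1, 258 for Reb1, 196 for Cbf1 and 101 for Mcm1, against 8.22, 9.35, 3.28 and 2.23 under shifts (adjusted permutation p = 0.002 for each). Rap1 ChIP-exo had a peak at 1 tRNA gene, against 1.52 under shifts. Of the 275 tRNA genes, 78 were reached by all 4 other ChIP-exo lists and 4 by none of them. In PB-exo the counts were 13 for Abf1, 2 for Cbf1, 4 for Mcm1, 33 for Reb1, 50 for Rap1 and 28 for Pho4, and none passed the test against the shifts. Small excesses passed in Abf1 Native PB-seq (17, against 9.09; adjusted permutation p = 0.0187), Reb1 Native PB-seq (11, against 3.34; 0.002) and Reb1 WhIP-exo (23, against 12.9; 0.0132). Of the Cbf1 ChIP-exo peaks at tRNA genes 1 of 230 had a PB-exo peak, against 22 of 957 for Abf1, 3 of 129 for Mcm1 and 49 of 558 for Reb1. The median score of the peaks at tRNA genes was 45 for Cbf1, 57 for Reb1 and 15 for Mcm1. Other peaks of the same lists had higher medians of 70, 133 and 29. For Abf1 the medians were 42 and 40.

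**Figure D4:**
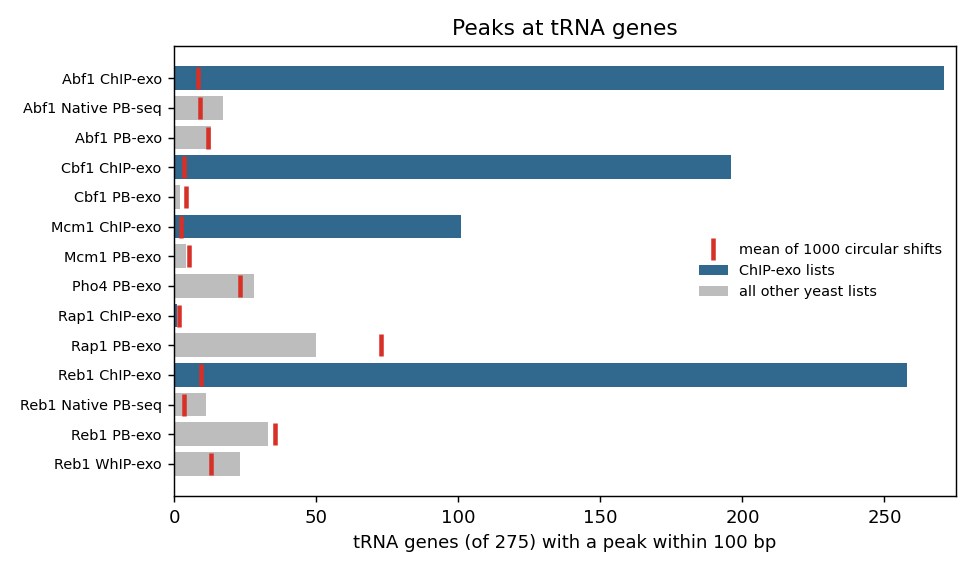
Number of the 275 tRNA genes with a listed peak within 100 bp, for the 14 yeast lists. Bars are observed counts, blue for ChIP-exo and grey for all other lists, and red lines the mean of 1000 circular shifts; 4 ChIP-exo lists reach between 101 and 271 genes and the Rap1 ChIP-exo list 1.

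Chromosome ends, where Rap1 binds the telomeric repeats, had a peak within 1 kb in all 5 ChIP-exo lists more often than under shifts. Of 32 ends, 22 had a Rap1 peak, 22 an Abf1 peak, 22 a Reb1 peak, 18 an Mcm1 peak and 9 a Cbf1 peak (adjusted permutation p = 0.002 for each). Rap1 had 29.5% of its ChIP-exo peaks within 1 kb of an end. In PB-exo, 21 ends passed for Reb1 (adjusted permutation p = 0.00875), 8 for Mcm1 (0.00747) and 7 for Cbf1 (0.002). Rap1 PB-exo had a peak at 22 ends, against 20.4 under shifts (0.497), Abf1 at 4 (0.818) and Pho4 at 7 (0.818). Reb1 Native PB-seq had 16, Reb1 WhIP-exo 19 and Abf1 Native PB-seq 11 (0.002 for each). For Rap1 PB-exo the shifts already reached most of the 32 ends, so the count of ends could show little enrichment. Of the peaks in that list, 208 of 17272 (1.204%) lay within 1 kb of an end, against 0.264% of the background positions. This difference in share was not tested. Of the 28 pairs of list and feature, 18 passed. An end set by the last listed peak holds a peak of that list without any enrichment, and how many ends were set so was not counted.

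ChIP-exo peaks of at least 3 factors came together at 303 positions, linked within 50 bp, against a mean of 0.875 under shifts (permutation p = 0.001). Without peaks at tRNA genes 96 positions remained in the count, against 0.388 under shifts. PB-exo peaks of at least 3 of the 5 factors came together at 289 positions, against 41.9 (permutation p = 0.001), and at 108 without pairs 3 bp apart, against 14.9. The shifts do not keep the concentration of peaks in promoters, at chromosome ends or at tRNA genes. These counts therefore do not show that the factors bound together.

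On MCF-7 DNA, Reb1 PB-exo gave 5177 autosomal peaks, from samples whose antibody label also names Rap1-TAP. Chromosome 20 held 712 of them (13.8%), 6.13 times its share of the autosomal span, chromosome 17 held 556 (10.7%, 3.77 times) and chromosome 3 held 567 (11.0%, 1.53 times). Chromosome 8 held 328 (6.34%, 1.21 times). By exact binomial tests with adjusted p, these 4 chromosomes lay above their share of the span and 13 below it, with chromosome 18 the lowest at 48 peaks (0.334 times). Shares sum to a whole, so an excess on some chromosomes lowers all others. When the other 18 were set against one another, a test added after the data were seen, 5 lay below their share, chromosomes 4, 10, 13, 18 and 22, with ratios from 0.474 to 0.761, and 6 above it. The span of each chromosome was taken from its first to its last listed peak. Pairs exactly 3 bp apart made up 31.3% of the list.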

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

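The tests of differences between factors, the tests on tRNA genes and the score-matched odds ratio of pairs 3 bp apart were chosen after the results were seen. The bounds for the coincidence of such pairs between lists were set before those values were computed, as was the bound for the tRNA positions of Cbf1 and Mcm1, while the share of such pairs in the Mcm1 list was brought in after.

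The excess of promoters among PB-exo peaks that were also bound in cells differed between the factors. On the log2 scale the odds ratio was 3.89 for Abf1, 3.00 for Reb1, 2.56 for Mcm1, 2.04 for Rap1 and 1.33 for Cbf1, a range of 2.56. Permuting the factor labels gave p = 0.001, the smallest that 1000 permutations can give. The labels were permuted over listed peaks of pooled lists. Several pairs of a site therefore counted separately, which makes p too small, and no spread between replicates entered. Permuted labels also even out baseline shares, so differences in baseline between the factors enter the test. Protein concentration in PB-exo was not the same for all factors, and depth and filter are unknown. Effects of these on the range were not separated from those of the factor. Under the 9 alternatives the range ran from 1.67 to 4.37 with the same p, but the order of the factors changed. Mcm1 was highest with 1000 bp promoters (3.95), Abf1 and Reb1 lay close without pairs 3 bp apart (3.00 and 2.90), Rap1 lay above Mcm1 without chromosome ends and rDNA (3.20 and 3.02), and Rap1 was lowest at or above the median score of both lists (-0.01).

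The share of peaks at tRNA genes in ChIP-exo against PB-exo also differed between the factors, with a log2 odds ratio of 7.12 for Cbf1, 5.83 for Abf1, 5.69 for Mcm1, 5.03 for Reb1 and -0.34 for Rap1, a range of 7.46 (permutation p = 0.001, the smallest possible). The limits of the permutation given above hold here as well. Few peaks lie behind some ratios, with 2 Cbf1, 4 Mcm1 and 14 Abf1 PB-exo peaks and 1 Rap1 ChIP-exo peak at tRNA genes. The order of the factors other than Rap1 is therefore uncertain. Binding of each factor to tRNA genes by their DNA sequence was argued against as the main cause, since the PB-exo lists of the 4 factors reached 52 tRNA genes in sum, against a mean of 56.4 and a highest value of 80 under shifts, although a small part for Abf1 and Reb1 stays open, because Abf1 Native PB-seq (17, against 9.09), Reb1 Native PB-seq (11, against 3.34) and Reb1 WhIP-exo (23, against 12.9) reached more than under shifts. A background carried alike by every ChIP-exo list was argued against by the Rap1 list, which reached 1 tRNA gene (mean 1.46, highest 6), although a filter that differed for Rap1 stays open. Positions on tRNA genes common to the factors, whichever was tagged, are a candidate explanation, because 45.9% of the Abf1 peaks there (439 of 957, interval 42.7 to 49.0) had a Reb1 peak within 10 bp, against 15.5% on average and 19.1% at most under random placement in the same windows, and all 5 other pairs of the 4 lists also lay above every placement, from 29.5% of Mcm1 peaks with a Cbf1 peak (14.7% at most) to 79.1% of Cbf1 peaks with an Abf1 peak (32.6% at most), although the placements do not keep a preference for a part of the gene and the lists differ in median position, from 15 bp upstream of the 5′ end for Cbf1 to 35 bp downstream for Abf1. Such positions may reflect recruitment of these factors to tRNA genes in cells or a crosslinking background of active tRNA genes, and as the control samples were not analysed here, these were not separated.

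Pairs whose peaks were exactly 3 bp apart, a spacing that no comparison of the report was about, made up 69.5% of the Abf1, 28.8% of the Rap1 and 11.8% of the Reb1 PB-exo list and 31.3% of the human list, with no control list used here to set them against. Footprints at sites like those of the other pairs were argued against, since at matched scores (10 equal parts of each list) such pairs had a ChIP-exo peak less often (pooled odds ratio 0.127, interval 0.0996 to 0.163). Location was not matched. Such pairs lay in coding spans more often than others, at 79.8% against 46.2% for Abf1, 75.8% against 61.5% for Rap1 and 74.5% against 53.2% for Reb1. PB-exo peaks in coding spans seldom had a ChIP-exo peak, so a part for location in this odds ratio stays open. Positions prone to such pairs in any library met the bound set beforehand, as 46.4% of the Abf1 pairs of this kind (632 of 1361, interval 43.8 to 49.1) had a Rap1 or Reb1 pair of this kind within 10 bp, against 0.975% on average and 4.85% at most under shifts, but a bound on coincidence says nothing of lists that lack such pairs, and the Mcm1 list, with 0.775%, argues against every library alike unless its filter or depth differed. Positions prone to such pairs in the libraries of Abf1, Rap1 and Reb1 but not in every library remain a candidate explanation, since 36.7% of the Reb1 pairs of this kind (303 of 826, interval 33.5 to 40.02) had a Rap1 pair of this kind within 10 bp, against 0.860% on average and 2.06% at most. Whether they arose from the reagents, the sequencing or a mode of binding in vitro was not tested, and the sequence at these positions was not searched.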

How the results depend on the processing

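The removal of pairs 3 bp apart, the removal of peaks at tRNA genes and, for the promoter odds ratios, the removal of chromosome ends and rDNA and the median score in both lists were added after the results were seen; the other alternatives were fixed before. Of 153 alternative values over 24 results, 150 kept their direction and their side of the threshold or, for counts, stayed within 1.5 times. All 97 planned values did so. The promoter odds ratio of Rap1 fell from 4.11 to 0.985 (adjusted p = 0.943) among peaks at or above the median score of both lists, and the cause was not tested. The other 2 were counts of positions with 3 or more factors: in ChIP-exo the count was 96 in place of 303 without peaks within 100 bp of a tRNA gene, and in PB-exo 108 in place of 289 without pairs 3 bp apart, and in both the peaks removed account for the fall. Both stayed above all shifts (permutation p = 0.001, the smallest possible), which do not keep the concentration of peaks in promoters. Over the alternatives, the share of ChIP-exo peaks with a PB-exo peak ran from 10.6% to 24.2% for Abf1, 35.2% to 68.5% for Cbf1, 26.2% to 47.9% for Mcm1, 66.3% to 99.2% for Rap1 and 39.7% to 69.3% for Reb1. The lowest values for Cbf1 and Rap1 came from merged positions, which are means and can move apart. The promoter odds ratio ran from 8.07 to 20.6, 1.61 to 3.42, 3.95 to 15.8, 0.985 to 9.24 and 6.28 to 12.6 in the same order. Of the 20 enriched pairs of gene list and peak list, 19 were kept with 300 bp promoters (Rap1 PB-exo with glycolysis lost), 17 with 1000 bp (the same pair and the proteasome in Reb1 PB-exo and WhIP-exo lost), 19 at or above the median score (RNA polymerase subunits in Abf1 ChIP-exo lost), and all 20 without 3 bp pairs or without tRNA genes. Gained were ribosome biogenesis in Abf1 ChIP-exo (adjusted p = 0.0212) and PB-exo (0.0314) with 300 bp, and with 1000 bp RNA polymerase subunits in Abf1 PB-exo (0.0261) and glycolysis in Rap1 ChIP-exo (0.0114) and Reb1 WhIP-exo (0.0492). Ribosomal proteins in Reb1 PB-exo were depleted at or above the median score (odds ratio 0.462, adjusted p = 0.0238). Of 55 planned results, 32 that need a genome sequence (motifs, flanking bases, E-boxes), the counts at centromeres and every alternative on motifs were not run. No paired analysis was possible because each list pools the replicates of its group, and for the same reason no replicate was left out. Read depth is unknown, so a peak missing from a list sets no limit on binding.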

Other observations

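All tests in this part were chosen after the results of the report were seen, except that the bound for merged human peaks was set before its value was computed.

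Outside tRNA genes, chromosome ends and rDNA, all 10 pairs of factors had more ChIP-exo peaks within 50 bp of each other than under shifts (adjusted permutation p = 0.001 for each). The shifts do not keep the concentration of peaks in promoters, snoRNA genes were kept, and a background of open chromatin was not tested, so these counts of coincident peaks in separate lists do not show that the factors bound together. Abf1 peaks had a Reb1 peak in 377 of 1885 cases (20%, interval 18.3 to 21.9; 16.4 times chance), Rap1 peaks an Abf1 peak in 45 of 218 (20.6%, interval 15.8 to 26.5; 20.3 times) and Cbf1 peaks a Reb1 peak in 106 of 663 (15.99%, interval 13.4 to 19.0; 13.9 times). The lowest share was 3.33% (14 of 420), for Mcm1 peaks with a Cbf1 peak. On genomic DNA, 7 pairs passed and 3 with Mcm1 did not: Mcm1 peaks had an Abf1 peak in 1.52% (13 of 854, chance 1.52%, adjusted permutation p = 0.527), a Cbf1 peak in 1.17% (adjusted p = 0.0900) and a Rap1 peak in 12.6% (chance 11.2%, adjusted p = 0.143). Abf1 PB-exo peaks had a Rap1 peak in 1016 of 1875 cases (54.2%; 4.82 times chance), in lists where pairs 3 bp apart were 69.5% and 28.8%.

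Genes of small nucleolar RNAs, which guide the modification and processing of ribosomal RNA, carried ChIP-exo peaks of 3 factors. Of 76 such genes, 35 had an Abf1 peak within 100 bp (2.75 under shifts, adjusted permutation p = 0.00700), 24 a Reb1 peak (3.32 under shifts, 0.00700) and 6 an Mcm1 peak (0.747 under shifts, 0.00933). Cbf1 ChIP-exo peaks stood at 0 and Rap1 ChIP-exo peaks at 1. No in vitro list passed: Reb1 Native PB-seq reached 5 (1.29 under shifts, adjusted permutation p = 0.0735), Reb1 WhIP-exo 10 (4.63 under shifts, 0.0756), Abf1 PB-exo 5 and Reb1 PB-exo 11.

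The position of the ChIP-exo peaks of 4 factors along the tRNA genes was counted from the 5′ end. Counting each peak once per tRNA gene within reach, 176 of 233 Cbf1 peaks (75.5%) lay within 30 bp upstream of the 5′ end, against 53 of 129 for Mcm1 (41.1%), 230 of 567 for Reb1 (40.6%) and 286 of 978 for Abf1 (29.2%). The difference between the factors was not tested.

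The peaks of Reb1 on MCF-7 DNA were uneven over the autosomes, with 7.60 times as many per Mb on the highest as on the median autosome. Piling of many peaks at a few repeated positions was argued against as the whole cause, because the ratio was 3.09 after peaks within 10 kb were merged, which left 4192. A candidate explanation is a higher copy number of some segments in the DNA of this cell line, since 22 of the 28 windows of 1 Mb with 10 or more peaks adjoined another such window, against 0.529 on average and 6 at most under random placement. These windows held 1335 peaks (25.8%) on 5 chromosomes, with a median score of 104 against 96 elsewhere. The random placement drew windows evenly from all autosomes, so an excess on a few chromosomes by itself raises the number that adjoin. The count of adjoining windows therefore does not separate copy number from other causes of the unevenness. Copy number was not measured and the density of Reb1 sequences was not searched, so either may contribute.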
